A study of Mus musculus with 4 samples.

How the data were processed

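Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in female germ cells of C57BL/6 mouse embryos at embryonic day 15.5. Per the labels' protocols, the cells were sorted by the fluorescence of an Oct4-EGFP reporter, and tagmented DNA was amplified with indexed primers and purified on beads. There were 4 libraries in 2 groups, 2 from control embryos (Control 1 and Control 2) and 2 from embryos with a conditional knockout of Snf5 (Snf5 CKO 1 and Snf5 CKO 2). Snf5 is the protein encoded by Smarcb1, a core subunit of the SWI/SNF chromatin remodelling complex. Groups and replicate numbers were taken from the labels. The labels do not say whether the replicates of a group came from separate animals, so the spread between them may be technical.

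Per the submitters' processing notes, the genome build was mm10, reads were 50 bp long, and Trim Galore 0.6.5, Bowtie2 2.4.2, SAMtools 1.10, Picard 2.25.2 and MACS2 2.2.7.1 were used, with no role or order given for each. The peak calling thresholds, the treatment of duplicate and mitochondrial reads and any shift of read ends for the transposase are not given in the sources used here. The authors deposited a list of broad peaks for each library, called separately. In these deposited lists each peak has a position, a score that equals 10 times the −log10 q cut to a whole number, a fold enrichment over the local background, and the −log10 p and −log10 q given by the authors' peak caller. The smallest deposited −log10 q was 1.00 in Snf5 CKO 1 and between 1.01 and 1.02 in the others. No read counts were used here, so the sequencing depth of each library is unknown, and a region without a peak may have been open below the level that a library could detect. Fold enrichment and −log10 q served only to describe, rank or filter peaks within a list.

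The 4 lists were merged wherever peaks overlapped by at least 1 bp, and each merged region was given the libraries that held a peak in it. A region was called kept when all 4 libraries had a peak, lost when both controls and neither Snf5 CKO library had a peak, and gained in the reverse case. Protein-coding genes were placed from the RefSeq gene table of GRCm38.p6, the primary assembly of mm10, as 21887 genes. That table gives gene starts and ends with no strand or transcript start, so the planned windows around transcription start sites were replaced by windows of 1 kb on each side of both annotated gene ends. A gene was called open in a library that had a peak of at least 1 bp in either window, and lost, gained or kept by the same rule as for regions. The words lost and gained promoter refer to these gene-end windows, which can also catch peaks at a 3′ end and can miss a transcription start inside a gene. Of the 21887 genes, 12315 had peaks at 1 end, 2220 at both ends and 7352 at neither. Windows shifted by 50 kb counted 9.77% to 14.4% of genes as open in the 4 libraries, against 56.4% to 63.3% for the windows at the genes.

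Counts of lost and gained regions and genes were set beside the same counts for the other 2 ways of splitting 4 libraries into 2 pairs. With 2 libraries against 2 there are 3 splits, and the smallest two-sided permutation p is 0.333. Gene lists and the share of regions near gene ends were compared by two-sided Fisher's exact tests, with the sample odds ratio and its exact 95% interval, against regions or genes that could have been lost or gained. These tests treat genes or regions as units and say nothing about the spread between animals. The 17 gene lists were fixed before the data were examined, and p-values were adjusted over the lists by the method of Benjamini and Hochberg with a threshold of 0.05. The lists cover 4 sets of meiotic genes, whose union is called the meiotic list, and retinoic acid and BMP response, primordial germ cell and pluripotency, germline genome defence, oocyte growth and follicle formation, SWI/SNF subunits, male germ cell, ovarian supporting cell, ovarian stroma and mesenchyme, endothelium and blood, p53 response, Hox genes, ribosomal proteins and olfactory receptors. Meiosin was found through its synonym, the symbol Bhmg1.

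Genes were named by a rule fixed before the data were examined. It names Smarcb1, Stra8 and Meiosin, up to 4 lost and 4 gained members of every list, the 10 lost and 10 gained genes with the highest fold enrichment in the weaker of the 2 libraries that had the peak, and 3 lost and 3 gained regions away from gene ends by the same measure. Other genes are named only as members of a fixed list or are said to have been chosen after their values were seen. The length of the peaks touching the windows was compared at genes kept in all 4 libraries. This measure, a rule that counts a gene as open when a library has a peak anywhere in the merged region touching its window (the whole-region rule), the restriction to genes with peaks at 1 end, and a −log10 q of at least 10 for presence were all added after the data had been examined.

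Other settings, fixed before the data were examined, were a −log10 q of at least 3 in every library or for presence alone, lists cut to the 28625 strongest peaks, coverage of 50% of a region or 500 bp of a window, autosomes only, windows of 500 bp and 2 kb, strata of control signal, a replicate block and leaving out each replicate in turn. Some results for single genes and for lists that rest on them are not reported here, so fewer lists are described than were tested, while counts of lists past the threshold cover all lists tested. CpG content of promoters and motifs in distal regions need a genome sequence and were not run. The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated lists made from the 19425 kept regions, with 1012 regions made lost and 600 made gained. The region comparison recovered 94.7% of the lost and 96.5% of the gained regions, 1.74% of its lost calls were false, and the planted gene list had an odds ratio of 3.39 (adjusted p = 0.0168, Fisher's exact test) with 0 other lists past the threshold. In a simulation with no change, 12 regions were called lost, 16 gained and 0 lists passed. Each simulated library missed 2% of its regions and was given 3000 private peaks. The deposited lists differed far more, with 14042 merged regions held by Snf5 CKO 1 alone. The simulations therefore test the scripts and do not estimate the rate of false calls in these data.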

Results

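ATAC-seq peak lists were compared between sorted female germ cells from control embryos and from Snf5 CKO embryos at embryonic day 15.5, a stage at which female germ cells are in meiotic prophase. The series title asks how SWI/SNF acts on meiotic gene activation, promoter remodelling and Meiosin. There were 2 libraries in each group. Control 1 held 39465 peaks over 27.4 Mb and Control 2 held 36730 peaks over 25.2 Mb. Snf5 CKO 1 held 45422 peaks over 24.3 Mb and Snf5 CKO 2 held 28625 peaks over 16.9 Mb. The mean number of peaks was 38098 ± 1934 (SD, n = 2) in controls and 37024 ± 11877 (SD, n = 2) in Snf5 CKO, a difference smaller than the spread between replicates. Covered length averaged 26.3 ± 1.54 Mb (SD, n = 2) and 20.6 ± 5.19 Mb (SD, n = 2). Read depth is unknown, so the number of peaks per library has no depth to be scaled by.

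Smarcb1, which encodes Snf5, had a peak at its higher-coordinate end in both controls and none in either Snf5 CKO library, which checks the labels. The gene lies at chromosome 10, 75896769 to 75921614. The control peaks spanned 75921290 to 75922018 in Control 1, with a fold enrichment of 4.37 in the authors' list, and 75920997 to 75922135 in Control 2, with a fold enrichment of 4.19. Of the 26 genes for SWI/SNF subunits, 24 were open in all 4 libraries and Smarcb1 was the only member lost (adjusted p of the list 1, Fisher's exact test). Smarcd3 was open in 3 libraries and had no peak in Snf5 CKO 2.

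The first question was which regions differed in accessibility between the genotypes. In 5010 regions both controls had a peak and neither Snf5 CKO library did, and in 3355 regions the reverse was found, beside 19425 regions with a peak in all 4 libraries. The regions lost with the highest fold enrichment away from gene ends were at chromosome 5, 139064625 to 139064961, inside Prkar1b, at chromosome 1, 79551714 to 79551959, 54910 bp from Ap1s3, and at chromosome 5, 120102634 to 120103258, 13255 bp from Rbm19. Their fold enrichments in the controls lay between 5.69 and 6.92. The strongest gained regions were at chromosome 11, 103990131 to 103990473, 4781 bp from Arf2, at chromosome 4, 99200878 to 99201396, inside Atg4c, and at chromosome 15, 47746980 to 47747479, inside Csmd3. Their fold enrichments in the Snf5 CKO lists lay between 8.03 and 9.15.

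The genotype split separated 8365 of the 66058 merged regions, while the other 2 splits of the libraries separated 1435 and 1603. The smallest two-sided permutation p that 3 splits allow is 0.333, so this comparison cannot pass 0.05. Shared bases as a fraction of all covered bases were 0.611 between the controls, 0.549 between the Snf5 CKO libraries and 0.420 to 0.499 across genotypes. With a −log10 q of at least 3 in every library, 3186 regions were lost and 2173 gained. With at least 3 for presence alone, 1650 were lost and 1531 gained, and with at least 10 for presence, 6 were lost and 24 gained. With the lists cut to the same length, 3170 were lost and 3071 gained. Requiring fewer libraries raised the counts: 9849 regions were lost without Control 1, 14523 without Control 2 and 7860 without Snf5 CKO 1, and 5243 were gained without Control 2 and 17436 without Snf5 CKO 2.

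**Figure D1:**
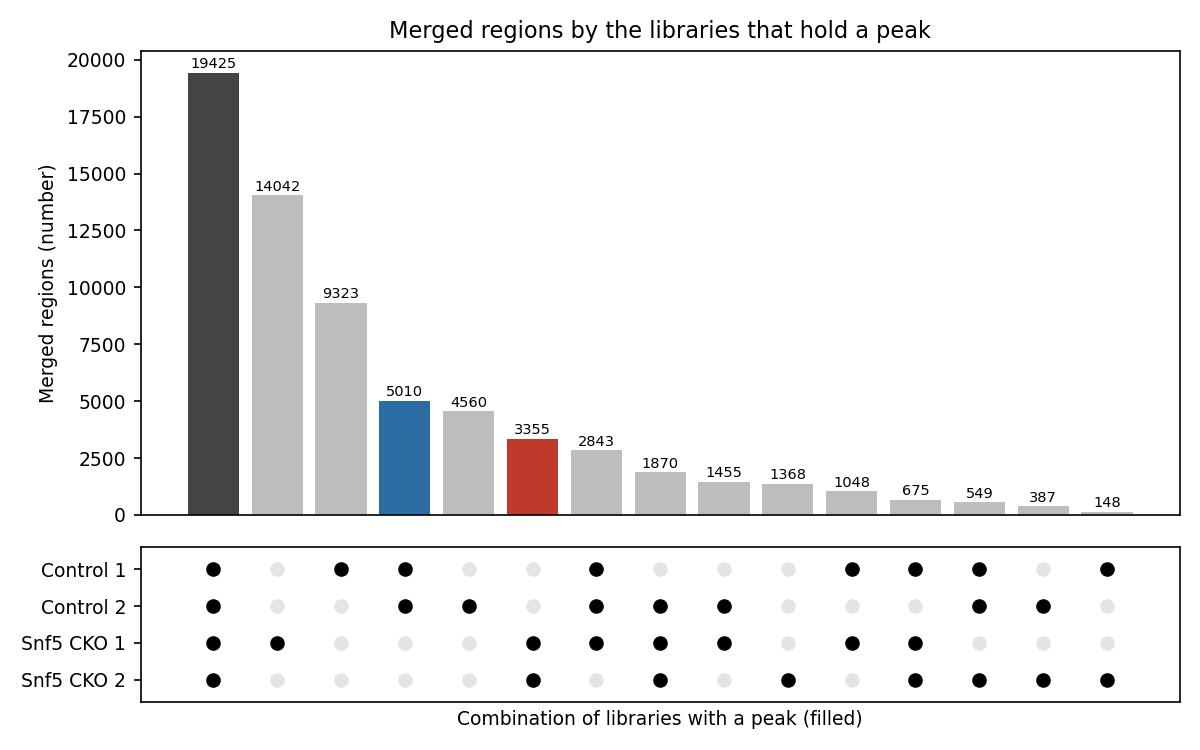
Merged regions (number, vertical axis) for each combination of the 4 libraries that hold a peak, shown by filled circles. Kept regions (dark bar, 19425), lost regions (blue, 5010) and gained regions (red, 3355) are coloured, and the other combinations that divide the libraries into pairs hold 148 to 1455 regions.

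Lost and gained regions lay mostly away from gene ends, while kept regions clustered at them. Of the lost regions, 16.7% lay within 1 kb of an end of a protein-coding gene, 48.6% elsewhere in a gene and 34.7% between genes. Gained regions were still more distal, with 3.90% near a gene end, 34.2% in gene bodies and 61.9% between genes. The kept regions held 56.4% near a gene end, 19.6% in gene bodies and 24.0% between genes. The odds of lying near a gene end were lower for lost than for kept regions (odds ratio 0.154, 95% interval 0.142 to 0.167) and lower for gained than for kept regions (odds ratio 0.0314, 95% interval 0.0261 to 0.0375). Regions shared by 1 control and 1 Snf5 CKO library alone were also mostly distal, with 4.91% to 9.46% near a gene end in the 4 such combinations, so a low share was not particular to lost and gained regions. Median width was 591 bp for lost, 452 bp for gained and 1071 bp for kept regions.

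Lost regions were unevenly spread over the chromosomes. Per kept region there were 0.112 lost regions on X, and 0.222 on chromosome 7 to 0.337 on chromosome 11 among the autosomes. Gained regions per kept region numbered 0.203 on X, within the autosomal range of 0.0984 on chromosome 11 to 0.235 on chromosome 1. In all, 108 lost regions (2.16%) lay on X, against 4.96% of kept regions, an odds ratio of X against autosomes of 0.421 (95% interval 0.341 to 0.516, two-sided Fisher's exact test, p = 1.11e-20 with regions as units). This comparison was chosen after the data had been examined.

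**Figure D2:**
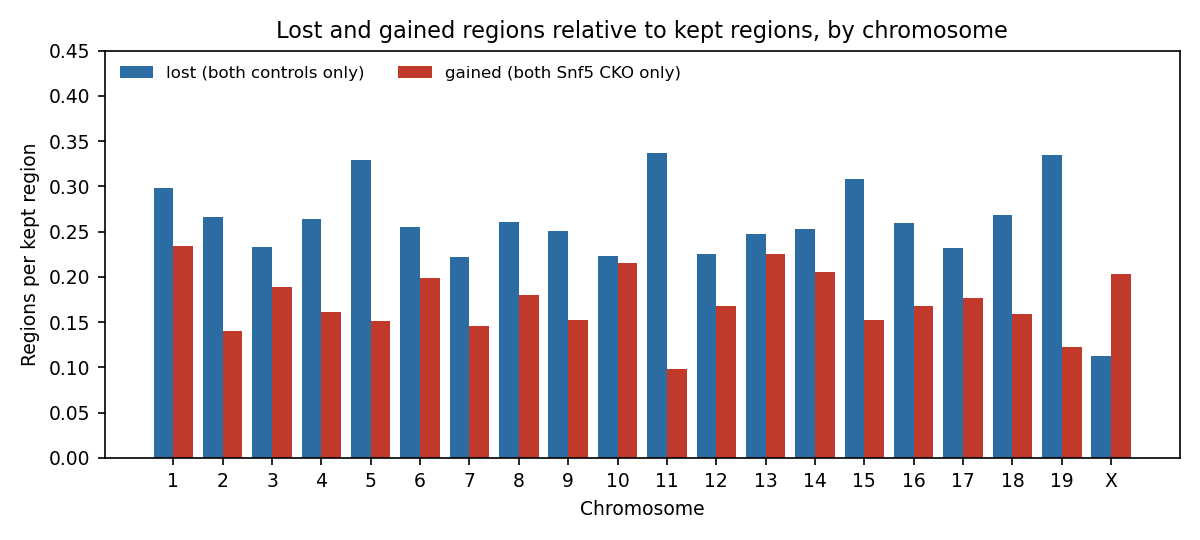
Lost regions (blue) and gained regions (red) per kept region (vertical axis) on each autosome and on X. Lost regions per kept region are 0.112 on X and 0.222 to 0.337 on the autosomes.

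The second question was whether promoters closed or opened in the knockout. Of the 13421 genes open in both controls, 12030 (89.6%) were open in all 4 libraries and 650 (4.84%) were lost in both Snf5 CKO libraries, while 41 genes closed in both controls were gained. The other 2 splits separated 60 and 110 genes, against 691 for the genotype split. Of the 650 genes, 71 still had a Snf5 CKO peak outside the window in a merged region that touched it, and under the whole-region rule 595 genes were lost, 579 of them shared, and 40 gained, 37 of them shared. Requiring a −log10 q of at least 3 for presence left 285 lost and 23 gained genes. With at least 3 in every library 82 genes were gained, and with lists of the same length 103. With 500 bp of the window covered 1122 genes were lost. Leaving out Control 2 gave 985 lost and 123 gained genes, leaving out Snf5 CKO 1 gave 1274 lost, and leaving out Control 1 or Snf5 CKO 2 gave 76 or 306 gained.

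The lost genes with the highest control fold enrichment were 9430038I01Rik, Mknk1, Vmn2r87, Iqca, Fads6, Rc3h2, Ruvbl2, Mroh7, Rps27l and BC028528. Of these 10, only Iqca was also lost under the whole-region rule, and its control peaks, at chromosome 1, 90153388 to 90153696 and 90153390 to 90153665, had fold enrichments of 5.67 and 6.28. The other 9 had Snf5 CKO peaks in the same merged region, among them the essential helicase gene Ruvbl2 and the ribosomal gene Rps27l. The 10 strongest lost genes under the whole-region rule, chosen after their values were seen, were Iqca, Ccdc43, Adgre5, Zfp287, Chil1, Tgfbi, Ccdc152, Gm7102, Gjb6 and Pik3ap1. Tgfbi, an extracellular matrix gene at chromosome 13, 56609586 to 56639359, had fold enrichments of 5.08 and 4.94 in the controls. Gjb6, a gap junction gene at chromosome 14, 57123301 to 57133611, had 4.86 and 5.06.

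The gained genes with the highest fold enrichment were Csrp1, Enpp3, Aadat, Drc7, Rfx5, Gm5771, Dusp26, Psg23, Tmem14a and Gm53057. All of these except Rfx5 were also gained under the whole-region rule. Csrp1, a gene for a LIM-domain protein at chromosome 1, 135720063 to 135752229, had fold enrichments of 5.98 and 5.71 in the Snf5 CKO lists. Enpp3, an ectoenzyme gene at chromosome 10, 24773814 to 24836195, had 5.55 and 5.75, and Aadat, a gene for an aminotransferase at chromosome 8, 60505843 to 60545677, had 4.93 and 5.54.

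The third question was whether meiotic promoters lost their accessibility. Most meiotic genes kept a peak: of the 78 genes on the meiotic list, 69 were open in both controls, and 65 of these (94.2%) were open in all 4 libraries. Rarg, a retinoic acid receptor gene at chromosome 15, 102234938 to 102257522, was the only member lost, with a fold enrichment of 2.74 in the weaker control list and no Snf5 CKO peak. The call of Rarg as lost ended with a −log10 q of at least 3 in every library or for presence alone. It also ended with lists of the same length. No member of the meiotic list was gained, and 8 had no peak within 1 kb of either gene end in any library. Among them were Spo11, which encodes the enzyme that makes meiotic double-strand breaks, and Stag3, a meiotic cohesin gene. The windows do not cover transcription starts inside a gene, so this does not show that their promoters were closed. The odds of loss did not differ detectably from those of other open genes (odds ratio 0.288, 95% interval 0.00717 to 1.66, p = 0.263, two-sided Fisher's exact test). When 500 bp of the window had to be covered, the odds ratio was 1.14 (p = 0.674, Fisher's exact test). Within strata of control signal the odds ratio was 0.46 and did not pass. All these tests count a peak as present or absent. A promoter that kept a peak may still have lost part of its signal. Such a fall was not tested, since no read counts were used.

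Within the meiotic list, the 16 genes of meiotic entry and its upstream regulators had 13 members open in all 4 libraries, with Rarg lost and Rara without a peak in Snf5 CKO 2. All 14 synaptonemal complex and meiotic cohesin genes that were open in both controls stayed open, as did 32 of 33 genes of meiotic double-strand breaks and recombination, Ccnb1ip1 having no peak in Snf5 CKO 2. Of the 7 genes of meiotic telomere attachment and movement, 6 were open in all libraries and Majin had no peak in Snf5 CKO 1. None of these 4 lists passed the test for loss, each with an adjusted p of 1.

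Meiosin and Stra8, which encode partner transcription factors of meiotic initiation, were open in all 4 libraries. Meiosin (Bhmg1, gene identifier 243866, chromosome 7, 19098271 to 19118531) had peaks of 1727 and 2182 bp at its higher-coordinate end in Control 1 and Control 2, and of 726 and 864 bp in Snf5 CKO 1 and Snf5 CKO 2. Control 1 and both Snf5 CKO libraries had a second, separate peak farther out, beginning at 19119631, 19119571 and 19119569, while Control 2 had a single peak from 19118016 to 19120197. Fold enrichment was 3.25 and 3.37 in the control lists and 4.28 and 3.85 in the Snf5 CKO lists for the peak at the gene end. For the second peak it was 4.20 in Control 1, 6.79 in Snf5 CKO 1 and 6.02 in Snf5 CKO 2. Stra8 (gene identifier 20899, chromosome 6, 34920163 to 34939344) had peaks of 1094 and 233 bp near its lower-coordinate end in the controls and of 292 and 200 bp in the Snf5 CKO libraries. For Stra8 the Snf5 CKO lengths thus lay on both sides of the Control 2 value. Outside the window, farther into the gene, second peaks measured 291 bp in Control 2, 401 bp in Snf5 CKO 1 and 524 bp in Snf5 CKO 2. The Control 1 peak ran unbroken from 34920660 to 34921753. The lengths given for Stra8 therefore depend on where a peak was split and where the window ended.

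**Figure D3:**
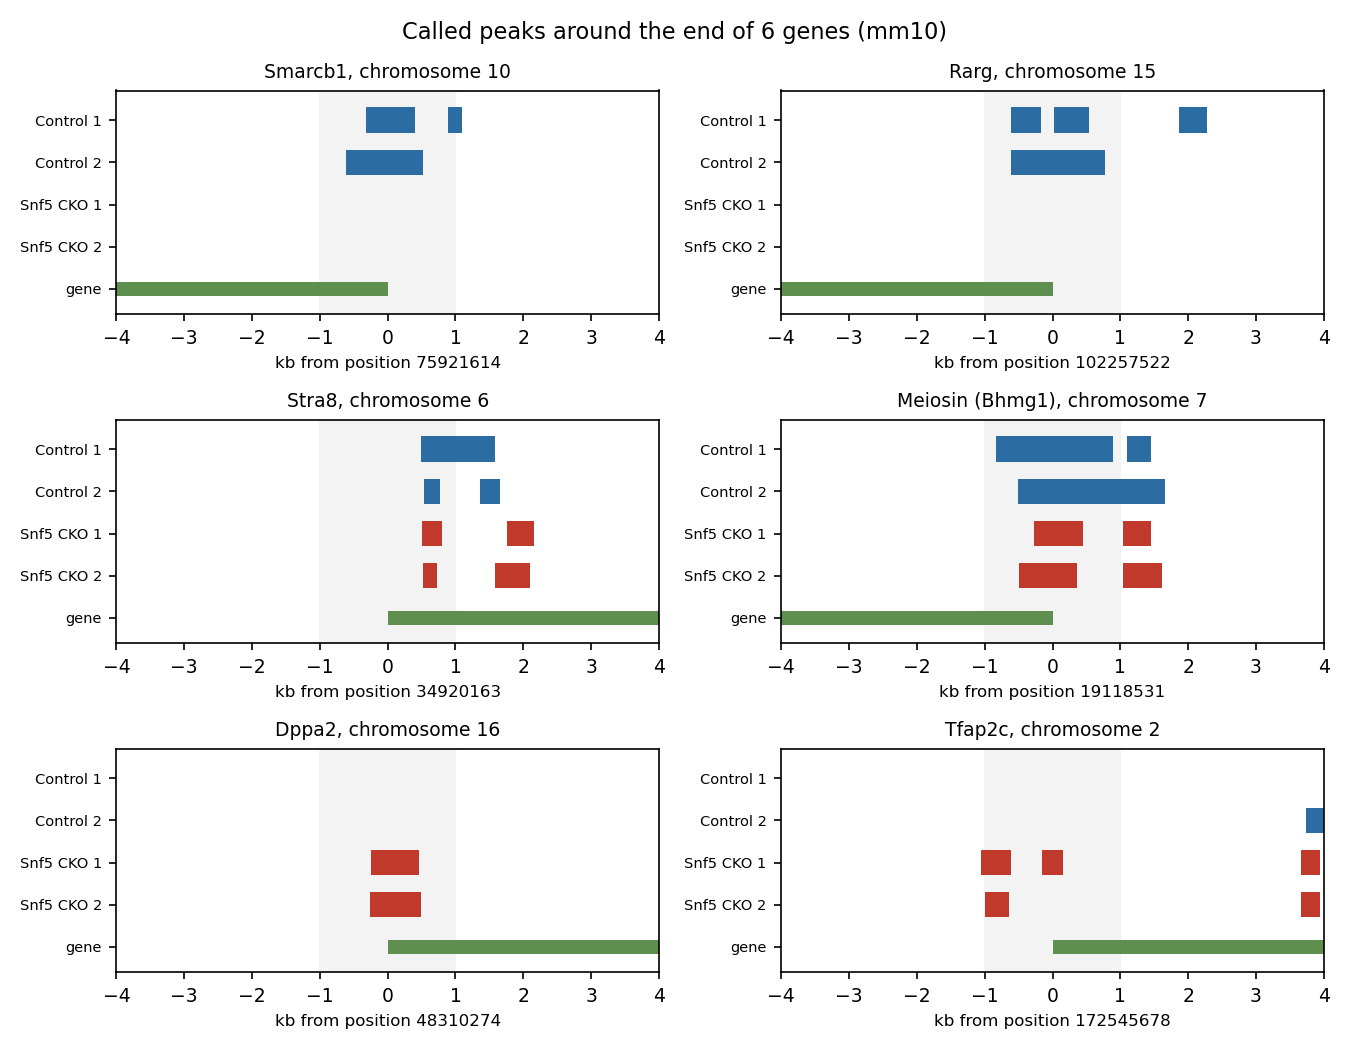
Called peaks (bars) within 4 kb of the gene end of 6 genes in each library, with controls in blue, Snf5 CKO in red, the gene body in green and the window of 1 kb on each side shaded; the horizontal axis is distance in kb. Smarcb1 and Rarg have peaks in the controls only, Stra8 and Meiosin in all 4 libraries, and Dppa2 and Tfap2c have peaks in the window in the Snf5 CKO libraries only.

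Peaks at promoters that stayed open were shorter in the knockout. Over the 12030 kept genes the median peak length was 1180 bp in Control 1, 1161 bp in Control 2, 889.5 bp in Snf5 CKO 1 and 833 bp in Snf5 CKO 2, so the library medians averaged 1171 ± 13.4 bp (SD, n = 2) in controls and 861 ± 40.0 bp (SD, n = 2) in Snf5 CKO. At 9295 genes (77.3%) both Snf5 CKO libraries had shorter peaks than both controls and at 154 genes both had longer peaks. Independent random orders at each gene would give 16.7% in each direction, but the peaks of 1 library can shift in length together. With 3 splits the smallest two-sided permutation p is 0.333. The other 2 splits gave 955 and 296 genes and 370 and 927 genes. The median log2 ratio of Snf5 CKO over control length was −0.41 and stayed between −0.46 and −0.36 in 11 alternatives, including lists of the same length. In kept regions away from gene ends the median log2 ratio of covered bases was −0.14, against −0.40 in kept regions near gene ends. This contrast was not matched on control length. The control medians were 688 and 650 bp away from gene ends and 1111 and 1091 bp near them. The length of a called peak also depends on depth and background, which are unknown here.

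The shortening ran through all 15 lists with at least 5 kept genes. The 65 kept meiotic genes had a median log2 ratio of −0.46, and 64 of them were shorter in Snf5 CKO by mean length. The 74 kept ribosomal protein genes had a median of −0.46, the 24 SWI/SNF genes −0.39 and the 14 p53 response genes −0.29. Genes of retinoic acid and BMP response had −0.82, ovarian stroma and mesenchyme −0.88 and germline genome defence −0.64. No list differed from random lists matched on control length after adjustment, the lowest adjusted p being 0.0900 for retinoic acid and BMP response (two-sided permutation test, 10000 random lists).

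**Figure D4:**
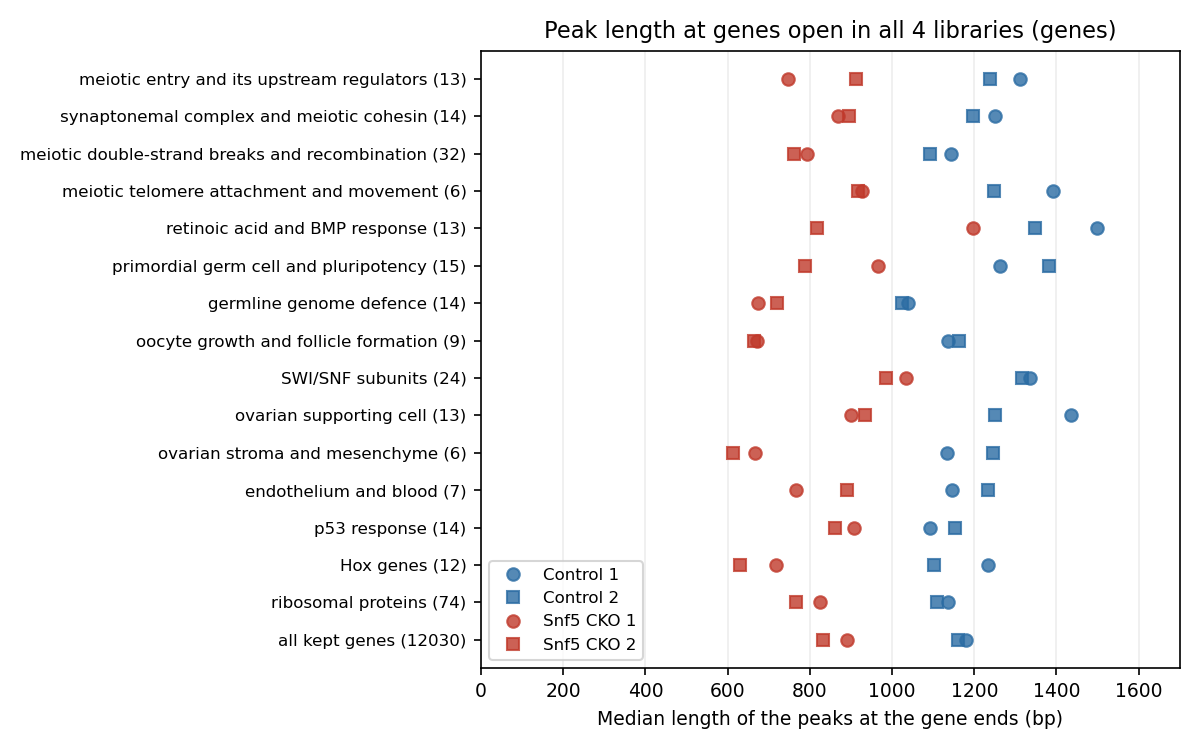
Median length of the peaks at gene ends (bp, horizontal axis) in each library, for all genes open in all 4 libraries and for each fixed list with at least 5 such genes (number in parentheses). Control 1 and Control 2 (blue) lie above both Snf5 CKO libraries (red) in every list shown, with 1180 and 1161 bp against 889.5 and 833 bp over all kept genes.

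Among the other lists, Hox genes and olfactory receptor genes were over-represented among lost promoters. Of the 22 Hox genes open in both controls, 6 were lost: Hoxb13, Hoxc9, Hoxc8 and Hoxc6, with lower control fold enrichments of 2.70 to 3.18, and Hoxa5 and Hoxa6, which share a peak (odds ratio 7.43, 95% interval 2.37 to 20.1, adjusted p = 0.00411, Fisher's exact test). Of 9 olfactory receptor genes open in both controls, 6 were lost, among them Olfr212, Olfr316, Olfr1419 and Olfr283 (odds ratio 39.7, 95% interval 8.44 to 245, adjusted p = 1.59e-05, Fisher's exact test). Hox genes encode transcription factors of body patterning, and olfactory receptor genes are mostly closed outside the nose, with 1071 of 1106 open in no library. The number open was 12 in each control, 26 in Snf5 CKO 1 and 2 in Snf5 CKO 2. Within strata of control signal the Hox odds ratio was 1.83 and no longer passed, and Hox genes did not pass with windows of 500 bp or 2 kb or with 500 bp covered. Olfactory receptors did not pass with a −log10 q of at least 3 in every library or for presence alone, with lists of the same length, or with 500 bp covered.

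Genes of germline genome defence also had lost members, without passing the adjusted test. Tdrd1, Tdrd9 and Gtsf1, which act in the piRNA pathway against transposons, were lost out of 17 open genes (p = 0.0463, adjusted p = 0.197, Fisher's exact test). Their control fold enrichments were 3.11 and 2.99 for Tdrd1, 2.29 and 2.56 for Tdrd9 and 4.92 and 3.04 for Gtsf1. The list's odds ratio of loss was 4.23 in the main setting and 19.0 within strata of control signal, without passing in either. It was 0.982 with a −log10 q of at least 3 in every library and 1.38 with lists of the same length. Ooep, a maternal-effect gene of oocytes, and Wnt5a, a signalling gene of the stroma list, were each the single lost member of their lists. Of 78 ribosomal protein genes open in both controls, 74 were kept in all libraries, and the lost pair, Rps27l and Rpl17, still had peaks in the same merged regions (adjusted p of the list 1, Fisher's exact test).

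Gained promoters included 2 genes of the primordial germ cell and pluripotency list. Dppa2 and Tfap2c, which encode factors of pluripotent and primordial germ cells, were gained out of 5 genes of their list that were closed in both controls (adjusted p = 0.00414, Fisher's exact test). Dppa2, at chromosome 16, 48310274 to 48319513, had fold enrichments of 4.32 and 3.71 in the Snf5 CKO lists, and Tfap2c, at chromosome 2, 172545678 to 172558622, had 4.39 and 3.63. In Snf5 CKO 2 the peak in the Tfap2c window, 172544687 to 172545036, did not reach the gene end. In the main setting no lost gene came from this list, and 15 of its 18 genes open in both controls were kept. Zfp42, Tcl1 and Fgf4, also open in both controls, had no peak in Snf5 CKO 2. With 500 bp of the window covered the list leaned toward loss without passing (odds ratio 4.80, p = 0.0101, adjusted p = 0.0856, Fisher's exact test). The call for gain ended with windows of 500 bp and with 500 bp of the window covered. No olfactory receptor gene was gained among 1091 closed ones, fewer than by chance (adjusted p = 0.0144, Fisher's exact test), beside 26 open in Snf5 CKO 1 and 2 in Snf5 CKO 2. This is a call that ended with a −log10 q of at least 3 for presence, with either other window and with 500 bp covered. None of the 15 genes of retinoic acid and BMP response open in both controls was lost in the main setting. With 500 bp covered their list also leaned toward loss without passing (odds ratio 6.00, p = 0.00506, adjusted p = 0.0856, Fisher's exact test).

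Most open genes of the somatic cell, p53 response and oocyte growth lists were kept. All 13 ovarian supporting cell genes open in both controls were kept, as were 7 of 9 endothelial and blood genes and 6 of 10 genes of ovarian stroma and mesenchyme. Of 15 open p53 response genes 14 were kept, and of 12 open genes of oocyte growth and follicle formation 9 were kept. Of all genes open in both controls 89.6% were kept. The stroma, endothelium and blood, and oocyte growth lists lay below that share. None of these 5 lists passed the adjusted test for loss or gain, each with an adjusted p of 1. With a −log10 q of at least 3 in every library, ovarian stroma and mesenchyme passed for loss (adjusted p = 0.00239, Fisher's exact test), and it also passed without Snf5 CKO 1 (adjusted p = 0.0452, Fisher's exact test).

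**Figure D5:**
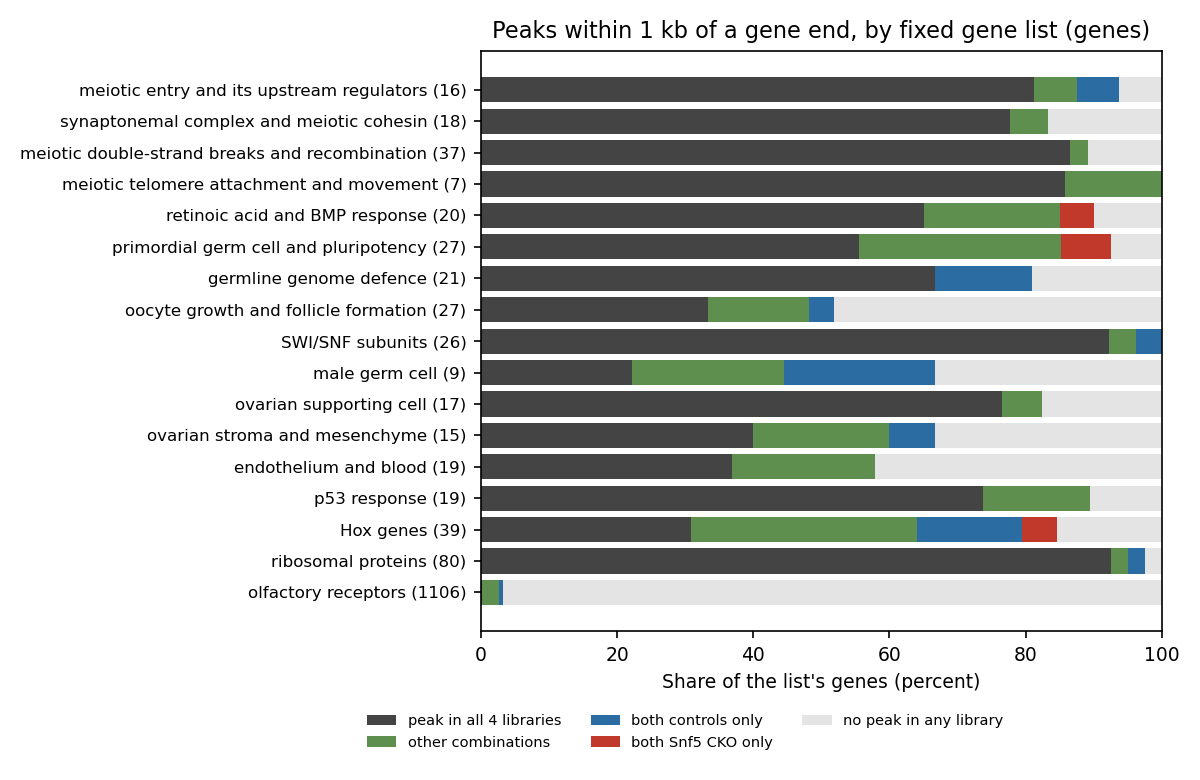
Share of each fixed list's genes (percent, horizontal axis; number of genes in parentheses) with a peak within 1 kb of either gene end in all 4 libraries, in both controls only, in both Snf5 CKO libraries only, in another combination, or in no library. Meiotic and ribosomal lists are mostly open in all 4 libraries, and 6 Hox genes are open in the controls only.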

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

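The tests in this part were chosen before their results were seen. Each library had peaks on the Y chromosome and on the mitochondrial genome, which no comparison was about. They entered the region counts, with 5 lost, 37 gained and 51 kept regions on Y and 2 kept regions on the mitochondrial genome. The female libraries held 83 Y peaks in Control 1, 107 in Control 2, 209 in Snf5 CKO 1 and 150 in Snf5 CKO 2. Each library had 2 peaks on the mitochondrial genome.

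Male cells in the sorted populations would have opened the ends of single-copy Y genes such as Ddx3y, Uty and Kdm5d, and 0 of 8 such genes had a peak in any library. Of the Y peaks, 83, 102, 198 and 144 in the 4 libraries lay beyond the last of those genes, and 1 to 4 per library touched a protein-coding gene. Male cells are therefore argued against as the source of the Y peaks as a whole. A candidate source is reads from sequences that the Y chromosome shares with other chromosomes, which was not tested because no reads were used here. No explanation of the Y peaks other than male cells was tested.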

How the results depend on the processing

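Tests with the whole-region rule, with genes open at 1 end, with a −log10 q of at least 10 and of peak length were chosen after the data had been examined. Of 129 alternative values of the 10 main results, 95 kept their direction and side of the threshold or stayed near the main value, 32 counts moved by over 1.5 times, 1 reversed and 1 newly passed the threshold. The lower odds of lost and gained regions near gene ends held in all 12 alternatives each, as did the shorter peaks at kept promoters in 11.

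Against 5010 lost and 3355 gained regions, a −log10 q of at least 3 in every library gave 3186 and 2173, at least 3 for presence alone 1650 and 1531, and at least 10 for presence 6 and 24. Lists of the same length gave 3170 lost regions. Against 650 lost and 41 gained promoters, at least 3 for presence gave 285 and 23, at least 3 in every library gave 82 gained, lists of the same length 103 gained and 500 bp covered 1122 lost. Leaving out a replicate gave 5562 to 14523 lost and 4047 to 17436 gained regions, and 767 to 1274 lost and 57 to 306 gained promoters, since fewer libraries were then required.

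The meiotic odds ratio of 0.288 reversed to 1.14 with 500 bp covered (p = 0.674, Fisher's exact test). The replicate block, with Control and Snf5 CKO libraries paired by number, gave 0.423 and passed the threshold, but each gene then entered both strata, which makes its p too small. Deviations of same-numbered libraries correlated at −0.0499 over 66058 regions. Every region holds at least 1 peak and list lengths differ, so this value cannot show whether the numbers paired the libraries. The split that joins same-numbered libraries separated 1435 regions as deposited and 1361 with lists of the same length. The split that joins Control 1 with Snf5 CKO 2 separated 1603 and 1021. Region and promoter counts cannot change under the block.

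Against 2 lists among lost promoters, presence at a −log10 q of at least 3 left 1, lists of the same length 1, windows of 500 bp 1, strata of control signal 1 and 500 bp covered 0, and leaving out a replicate gave 2 to 4. Against 3 lists among gained promoters, presence at 3 left 1, windows of 2 kb 1, windows of 500 bp 0 and 500 bp covered 0. Except where the number of libraries sets the count, the cause was not tested. CpG content, motifs and windows at the 5′ end alone were not run, as strand and sequence were not used here. Without depth, absence of a peak cannot be told from weak signal.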

Other observations

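Of the tests in this part, those on gonadal somatic cells, on the X odds ratio under other settings and on peaks with a −log10 q of at least 10 were chosen only after the result was seen. The lower share of X among lost than among kept regions, an odds ratio of 0.421, lay between 0.358 and 0.524 when each library was left out in turn. It was 0.570 with a −log10 q of at least 3 in every library and 0.433 with lists of the same length. Gained regions had an X odds ratio of 1.20 (95% interval 1.02 to 1.41). It was 0.868 (95% interval 0.734 to 1.03) within strata of gene density and promoter class. Within strata of peak strength it was 1.01 (95% interval 0.856 to 1.19). Without strata it was 1.38 (95% interval 1.12 to 1.67) with a −log10 q of at least 3 in every library. With lists of the same length it was 1.23 (95% interval 1.03 to 1.46). Leaving out each library in turn gave 1.18 to 1.37, each with a 95% interval above 1.

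Local gene density is argued against as the cause of the X pattern, since the odds ratio within strata of gene density and promoter class was 0.386 (95% interval 0.313 to 0.475). Peak strength in the controls is argued against too, with 0.372 (95% interval 0.299 to 0.464) within its strata. Male cells in the control libraries, which would lower X signal there, are argued against by 0 of 8 single-copy Y genes with a peak. A difference between genotypes in the state of the X chromosomes is a candidate explanation that stays open as an untested hypothesis.

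With the lists as deposited, the genotype split separated 8365 regions and the other splits 1435 and 1603. A difference in list length is argued against, since with lists of the same length the genotype split separated 6241 regions and the others 1361 and 1021, a ratio of 4.59. More gonadal somatic cells in the control libraries may still contribute. The pooled lists of supporting cells, stroma and endothelium or blood had 1 lost gene of 32 open ones, an odds ratio of 0.633 (95% interval 0.0155 to 3.81), and this interval keeps the question open although the Oct4-EGFP sort would remove such cells. Alone, the stroma list had an odds ratio of 2.18 in the main setting and did not pass. With a −log10 q of at least 3 in every library it passed for loss (odds ratio 27.6, adjusted p = 0.00239, Fisher's exact test). The supporting cell and endothelium or blood lists did not pass there. With 3 splits no share under 0.05 is possible.

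A hypothesis was that promoters of meiotic genes shortened more than other kept promoters. The meiotic list's median log2 ratio of peak length was −0.46, at percentile 21.2 of 10000 random lists matched on control length, whose central 95% range was −0.52 to −0.34. The data thus gave no evidence that meiotic promoters shortened more than others of like length.

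Strong peaks were shared unevenly. Of Control 1 peaks with a −log10 q of at least 10, 98.4% overlapped a peak in Snf5 CKO 1, 98.1% in Snf5 CKO 2 and 99.8% in Control 2. Of such Control 2 peaks, 99.8% overlapped in Snf5 CKO 1, 99.6% in Snf5 CKO 2 and 99.4% in Control 1. Of the 7492 such peaks in Snf5 CKO 1, 92.3% overlapped a peak in Control 1, 95.7% in Control 2 and 99.5% in Snf5 CKO 2. Of the 5986 in Snf5 CKO 2, 97.3% overlapped in Control 1, 98.6% in Control 2 and 99.0% in Snf5 CKO 1. In both Snf5 CKO lists the overlap was thus lower with Control 1 than with Control 2.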
